A study of Mus musculus with 2 samples.

How the data were processed

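H3K4me2 ChIP-seq peaks of mouse forebrain at embryonic day 14.5 were taken from 4 deposited peak lists: 1 for each of 2 biological replicates (24 and 34 embryos pooled), 1 for the pooled reads, and 1 of replicated peaks that derives from the other lists. The peaks lie on mm10 and were called against control alignments, per the file headers. The peak caller, the aligner and their settings are not given in the sources used here. Replicate 1's list derives from more input files than replicate 2's, per the file headers. Each peak has a start, an end and a summit offset, and a signal value, by the authors an enrichment whose relation to the control is not stated. The deposited score is a display value, and the -log10 p and -log10 q of each peak are the authors' own. These values were used only to describe, rank or filter peaks within a list. The files give no read counts, so the depth is unknown and no interval that needs it is given.

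Peaks on scaffolds were left out, 13 in the replicated list, which left 34850 replicated, 43836 pooled, 41104 and 42528 replicate peaks. All 34863 replicated peaks were identical to a pooled peak in every column. Of those on chromosomes, 31218 were overlapped by a peak of each replicate over 50% of either length, and 3632 were not. TSSs came from protein-coding transcripts of the GENCODE mouse annotation and sequence from the reference of the same build. For the genomic distribution of peaks, TSSs of all transcripts of any gene were used, noncoding ones included. A gene was marked if a peak overlapped 1000 bp either side of any of its TSSs. Coverage was the bp covered within 5 kb of a TSS, the largest over a gene's TSSs, and cannot exceed 10001 bp. Distal peaks lay over 2.5 kb from every TSS of any gene and were counted within 100 kb of the 5'-most TSS. A promoter was CpG-rich if 500 bp either side of any TSS had a CpG observed/expected ratio of at least 0.6 and a GC content of at least 50%.

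Replicates shared a peak at an overlap of at least 1 bp, set against 100 shuffles within chromosomes. The 22 gene lists were TFs of dorsal forebrain progenitors, TFs of cortical neurons, ventral forebrain, TFs of midbrain, hindbrain and spinal cord, Hox, radial glia, pan-neuronal, mature synapse, mature glia, choroid plexus, microglia, erythroid, endothelial, fibroblast and mural, liver, striated muscle, epidermis, housekeeping, cell cycle, histone methylation machinery, odorant receptor and vomeronasal receptor genes. Marking was tested by Fisher's exact test against all other protein-coding genes. Coverage (lists with at least 5 marked members) and distal peaks were tested by permutation with 100000 resamples, whose smallest p is 1e-05 for a list and 2e-05 for a difference between lists. Differences between lists have 95% bootstrap intervals from 10000 resamples of genes. The 15 motifs were counted in 500 bp at the midpoint of distal peaks and in as many windows of the same chromosome outside pooled peaks, matched on GC content in bins of 2%, with Fisher's exact test; 11 peaks had no match. All tests were two-sided, p-values were adjusted by Benjamini-Hochberg within each family, and the threshold was 0.05. Spreads of replicate values are SD with n = 2 and describe pools of embryos.

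Genes were named by rule: the 3 marked members of each list with the largest coverage and the first 2 unmarked ones alphabetically, the 10 genes with the largest coverage and the 10 with most distal peaks genome-wide, the 5 widest and 5 highest-signal peaks, the first 5 list members marked in 1 replicate only, and a few reference loci (Foxg1, Pax6, Dlx2, Hoxa9, Alb, Myod1, Gapdh). Where windows of genes in the genome-wide rankings overlapped, only the first gene alphabetically was kept. Alternatives were each replicate alone, the pooled list, -log10 q of at least 5, overlap of at least 50%, the 20000 peaks of lowest p, other windows (500 bp and 2 kb for marking, 2 kb and 10 kb for coverage, 50 kb and 250 kb or nearest TSS for distal peaks), the 5'-most TSS, CpG-rich promoters alone, and motif windows of 200 bp or at the summit. On simulated data, Fisher's exact test with planted lists of 20 genes called 279 of 300 high lists, 285 of 300 low lists and 8 of 500 null lists. The coverage test called 100 of 100 shifted and 7 of 100 null lists at an unadjusted threshold. Overlaps matched bedtools for 1150 of 1150 intervals. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, matplotlib 3.10.9, pysam 0.24.0 and bedtools 2.31.1 were used.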

Results

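Dimethylation of lysine 4 on histone H3 (H3K4me2), a mark found at promoters and enhancers, was mapped by ChIP-seq in mouse forebrain at embryonic day 14.5. At this age cortical neurons are born in the dorsal forebrain and GABAergic neurons in the ganglionic eminences of the ventral forebrain. The samples form 1 group of 2 biological replicates: replicate 1 pooled the forebrains of 24 embryos and replicate 2 those of 34, of both sexes. Peaks are given on genome build mm10. The replicates are separate pools, so their spread is between pools of embryos and not between embryos. The labels name 1 tissue and 1 age, and the comparisons are therefore between the replicates and between groups of genes within this tissue. The deposited lists held 41116 peaks for replicate 1, 42541 for replicate 2, 43849 for the pooled reads and 34863 replicated peaks. The files give no read counts, so the sequencing depth behind a peak is unknown. Gene lists, tests and alternatives were chosen before the data were examined, except where stated.

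Nearly the same genes carried H3K4me2 at a transcription start site (TSS) in both pools of embryos. Of 21826 protein-coding genes, 14239 were marked within 1 kb of a TSS in both replicates, 75 in replicate 1 only and 123 in replicate 2 only. Among 384 genes of the cell-type and reference lists, 9 were marked in 1 replicate only. The first 5 of these in alphabetical order were Hoxa10, Hoxa6, Hoxc10, Hoxd10 and Lum, of which 4 are Hox genes and Lum encodes a fibroblast matrix protein. Their covered length was short: Hoxa10 had 0 bp in replicate 1 and 192 bp in replicate 2, and Lum 0 and 276 bp. Over all peaks on the chromosomes, 87.4% of replicate 1's overlapped a peak of replicate 2 and 80.6% of replicate 2's overlapped a peak of replicate 1. The mean was 84.0% ± 4.82, where the SD is over these 2 directions of 1 comparison and not between pools. Shuffling 1 list within its chromosomes 100 times gave an overlap of 3.78% ± 0.0967 (SD over shuffles) and at most 4.01%. The base-pair Jaccard index was 0.798, against at most 0.0103 in the shuffles. Among the 20000 peaks of lowest p in each replicate, the mean overlap was 96.9%. The 5168 peaks of replicate 1 and 8246 of replicate 2 without a partner had median signal values of 3.18 and 3.53, whereas the shared peaks had 10.4 and 13.8 on the authors' scale.

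H3K4me2 was concentrated at promoters. Of 34850 replicated peaks on the chromosomes, 50.8% had their midpoint within 1 kb of a TSS of any gene, noncoding genes included. This was 7.98 times the 6.37% ± 0.126 (SD over 100 shuffles) of shuffled peaks. The replicates' own lists gave 47.6% ± 1.48 (SD, n = 2). Introns held 25.4% of the peaks against 40.2% of shuffled ones, intergenic sequence 19.3%, or 0.386 times the shuffled share, and exons 4.45% against 3.41%. The share at promoters was 43.4% in the pooled list, which also holds 8986 peaks outside the replicated list. The replicated peaks covered 49.6 Mb, or 1.82% of the chromosomes, with a median width of 1058 bp.

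A TSS was marked in 14310 of the 21826 protein-coding genes, or 65.6%, and in 14338 ± 33.9 by the replicates' own lists (SD, n = 2). Sequence separated the genes: 10779 of 10923 genes with a CpG-rich promoter were marked (98.7%), but 3531 of 10903 with a CpG-poor promoter (32.4%). The replicates' own lists gave 98.7% and 98.7% for CpG-rich promoters and 32.4% and 32.8% for CpG-poor ones. Gapdh, the glycolytic enzyme, carried the mark at a TSS that fell short of the CpG-rich definition (chromosome 6, 125161715 to 125166467), with 4198 bp covered within 5 kb. Alb, the serum albumin gene of liver (chromosome 5, 90460897 to 90476602), had 0 bp in all 4 peak lists.

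Genes of the forebrain, of radial glia and of neurons were marked almost without exception, and genes of several other tissues rarely. All 21 transcription factors (TFs) of dorsal forebrain progenitors, all 20 of cortical projection neurons and all 24 genes of the ventral forebrain had a marked TSS in each replicate. So did all 16 radial glia genes and all 19 pan-neuronal genes, and 21 of 22 genes of mature synapses, the exception being Vip, a neuropeptide of interneurons. Marking was rare among genes of liver (2 of 18), epidermis (2 of 15), red blood cells (2 of 15), microglia (2 of 15) and striated muscle (5 of 19). It was nearly absent from odorant receptors (3 of 1133) and vomeronasal receptors (1 of 328). The Hox genes, which pattern the hindbrain, spinal cord and trunk, were marked in 16 of 39 cases.

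Fisher's exact tests (two-sided, across genes of this tissue and not across animals) against all other protein-coding genes called 18 of the 22 lists, 10 higher and 8 lower. Adjusted exact p-values were 0.000695 for the dorsal forebrain TFs, 0.000788 for the cortical neuron TFs, 0.000154 for the ventral forebrain and 0.00311 for radial glia. The exact test gave an adjusted p = 1.99e-05 for the liver genes, 0.000154 for microglia, erythroid and epidermal genes alike, 0.00139 for striated muscle and 0.00296 for Hox. It took genes as independent, although neighbours such as those of a Hox cluster can share a peak. The housekeeping (20 of 20), cell cycle (20 of 20) and histone methylation machinery (19 of 19) lists were fully marked too, each with an adjusted exact p = 0.000788. TFs of midbrain, hindbrain and spinal cord were also marked more often than other genes, in 21 of 24 cases (adjusted exact p = 0.0358), and Evx1 and Evx2, homeobox genes of spinal interneurons, were among the exceptions. The following 4 lists were not called, those of mature glia (8 of 17), choroid plexus (8 of 12), endothelium (7 of 15) and meningeal fibroblasts and mural cells (10 of 14).

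The calls were then repeated within classes of promoter sequence. Among genes with CpG-rich promoters alone, 1 of 19 lists was called: Hox genes were marked in 12 of 28 cases, 42.9% against 98.8% of other CpG-rich genes (adjusted exact p = 1.79e-22). That p-value took Hox genes as independent, although they lie in clusters. With 98.7% of all CpG-rich genes marked, lists of this size could not be called higher there, so the lost higher calls say nothing about these lists. Among genes with CpG-poor promoters, an alternative added after the data had been seen, 6 of 21 lists were called. There, 11 of 12 mature synapse genes, 6 of 6 pan-neuronal genes, 5 of 5 radial glia genes and 4 of 4 cortical neuron TFs were marked, against 32.3% to 32.4% of other genes (adjusted exact p = 0.00024, 0.00604, 0.0149 and 0.0385). The few CpG-poor members of the dorsal forebrain TFs (2 of 2), ventral forebrain (3 of 3), housekeeping (3 of 3) and cell cycle lists (3 of 3) were all marked but too few for a call (adjusted exact p = 0.147 for the dorsal TFs and 0.0713 for the others). Marked members without a CpG-rich promoter included Dlg4, a scaffold protein of excitatory synapses, and Grin2b, an NMDA receptor subunit. Liver (5.88%), microglia (7.14%), epidermal (7.14%), erythroid (13.3%) and striated muscle genes (26.3%) were no longer called lower against the 32.4% of other CpG-poor genes (adjusted exact p = 0.054, 0.0748, 0.0748, 0.206 and 0.847). The Hox call was lost in the pooled list, where 51.3% of Hox genes were marked (adjusted exact p = 0.0753).

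**Figure D1:**
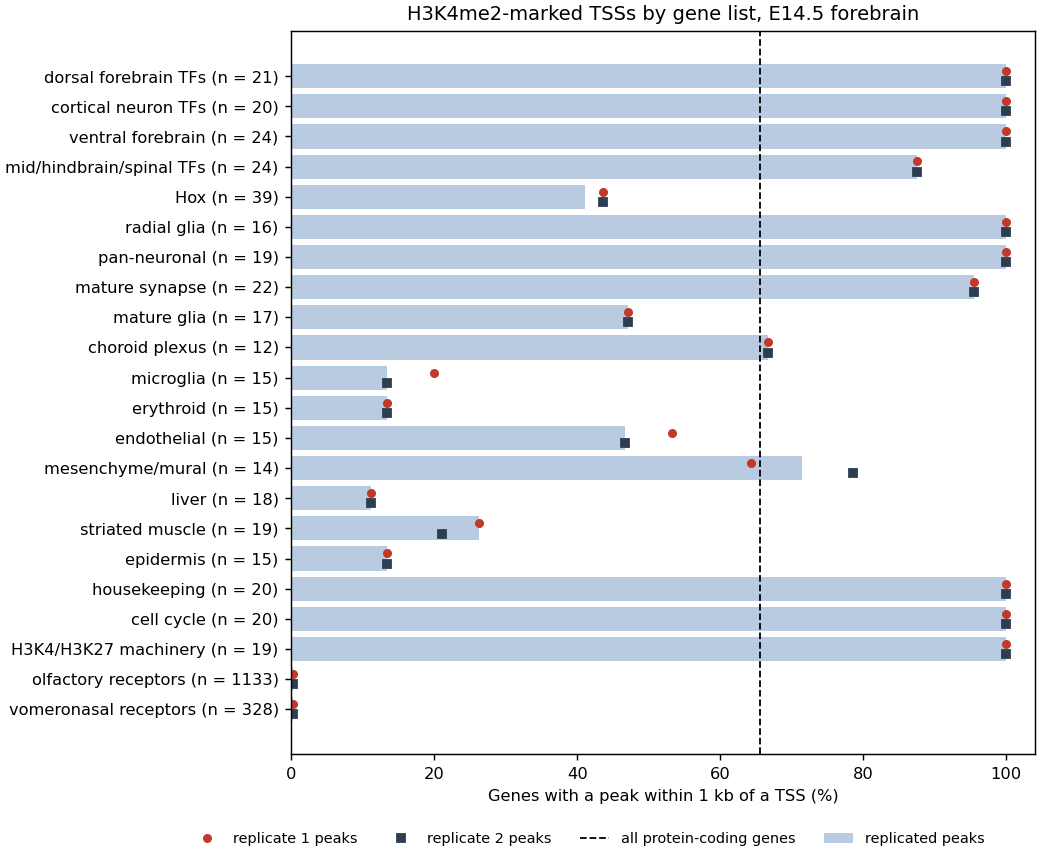
Percentage of genes in each of the 22 lists with a peak within 1 kb of a TSS: bars show the replicated peaks, circles and squares the replicates' own lists, and the dashed line the 65.6% of all protein-coding genes. The forebrain, radial glia and neuronal lists reach 95.5% to 100%, the Hox list 41.0%, and the liver list 11.1%.

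Around the TSSs of forebrain regulators, H3K4me2 formed broad domains. Replicated peaks covered on average 8435 bp of the 10001 bp around the TSS at the dorsal forebrain TFs, 7606 bp at the cortical neuron TFs and 7341 bp at the ventral forebrain genes, whereas other marked genes averaged 2799 to 2800 bp. Lhx2, Nr2f1 and Otx1 among the dorsal TFs, Bcl11a, Nfib and Pou3f3 among the cortical neuron TFs, and Six3 among the ventral genes were covered over the whole window. Pax6, a regulator of dorsal progenitors (chromosome 2, 105668900 to 105697364), was covered over all 10001 bp in each replicate. Foxg1, required for telencephalon development (chromosome 12, 49382660 to 49386861), had 9099 bp, and 7868.5 ± 467 bp in the replicates' own lists (SD, n = 2). Dlx1, a regulator of GABAergic neurons, had 9956 bp, and its neighbour Dlx2 (chromosome 2, 71543408 to 71546754) had 5741 bp.

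Radial glia genes (5206 bp), pan-neuronal genes (5332 bp) and mature synapse genes (4176 bp) lay between the regulators and the average gene. Examples were Fgfr2 with 8918 bp and Fgfr3 with 7522 bp, both FGF receptors, the RNA-binding protein gene Elavl4 with 9225 bp, neuronal tubulin Tubb3 with 7004 bp, and Slc32a1, the vesicular GABA transporter, with 9937 bp. Elavl4 had 8089 ± 1440 bp in the replicates' own lists, the widest spread among these genes, and Tubb3 6928.5 ± 0.707 bp (SD, n = 2). Housekeeping, cell cycle and methylation machinery genes had 3859, 3935 and 3989 bp. Their widest domains lay at Polr2a (6206 bp), at the G1 cyclins Ccnd2 (8666 bp) and Ccnd1 (6618 bp), and at the H3K4 methyltransferase genes Setd1b (9024 bp) and Kmt2a (6008 bp).

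Marked genes of the Hox, striated muscle and fibroblast and mural lists had shorter domains than other marked genes. Marked Hox genes averaged 932.5 bp, led by Hoxa7 (1622 bp) and Hoxd13 (1367 bp), and the 5 marked striated muscle genes 1369 bp, including 1204 bp at Myod1, the skeletal muscle regulator (chromosome 7, 46376474 to 46379099). The 10 marked genes of meningeal fibroblasts and mural cells averaged 1661 bp, with 4305 bp at Foxc1 and 2075 bp at Pdgfrb. Endothelial genes averaged 1796 bp and choroid plexus genes 1824 bp, and neither list was called. The mature glia list averaged 2844.5 bp, against 2807 bp in other marked genes, and included 6688 bp at Slc1a2, a glutamate transporter, and 6251 bp at Pdgfra, a receptor of oligodendrocyte precursors.

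In two-sided permutation tests of the list mean against random sets of other marked genes, 12 of 16 lists were called, 9 higher and 3 lower. For the dorsal, cortical, ventral, radial glia and pan-neuronal lists the permutation p was 1e-05, the smallest that 100000 resamples can give, and 3.2e-05 after adjustment. The adjusted permutation p was 5.33e-05 for Hox, 0.0233 for the fibroblast and mural list and 0.0413 for striated muscle. The adjusted permutation p was 0.75 for the mid- and hindbrain TFs, 0.944 for mature glia, 0.0705 for choroid plexus and 0.076 for endothelium. With CpG-rich promoters alone, 9 of these 12 calls were kept and the cell cycle list was no longer called (3645 bp, adjusted permutation p = 0.0815), while the fibroblast and mural and striated muscle lists had too few members to be tested. The striated muscle call was not tested without replicate 1, with stricter peaks or with 50% overlap in each replicate, which left too few marked members, and was lost in a 10 kb window and with CpG-poor promoters (1534 and 1369 bp, adjusted permutation p = 0.0644 and 0.254). The fibroblast and mural call was lost in both of these settings too (2197 and 1111.5 bp, adjusted permutation p = 0.103 and 0.116), the latter with 6 members against a mean of 2122.5 bp, and in a 2 kb window the mid- and hindbrain TFs were called lower (1937 bp, adjusted permutation p = 0.0413). In replicate 1 alone, without replicate 2, the choroid plexus (1565 bp) and endothelial (1361 bp) lists were called lower (adjusted permutation p = 0.0426 and 0.0246), as they were in a 2 kb window and at the 5'-most TSS.

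**Figure D2:**
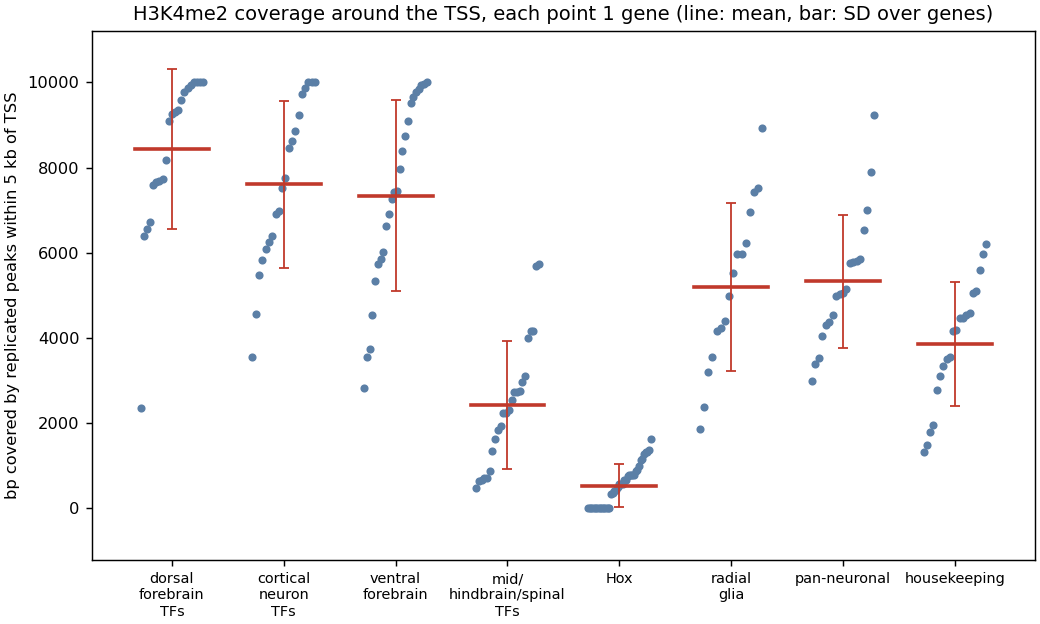
Base pairs covered by replicated peaks in the 10001 bp around the TSS for each gene of 8 lists, unmarked genes included: points are genes in rising order, lines the mean and bars the SD over genes. The dorsal and cortical TFs lie mostly above the highest mid- and hindbrain TF, Gbx2 at 5731 bp, and all of them above the highest Hox gene, Hoxa7 at 1622 bp.

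TFs listed for the forebrain and for neighbouring regions of the neural tube were compared directly. Both kinds mostly have CpG-rich promoters (19 of 24 in the second list) but were listed for different regions. Membership of a list does not mean that a gene is used in that region alone, and this was not tested. The 41 dorsal forebrain and cortical neuron TFs had a mean of 8030 ± 1935 bp covered (SD over genes), and the 24 TFs of midbrain, hindbrain and spinal cord 2424 ± 1503 bp. The difference was 5606 bp (bootstrap 95% interval over genes 4755 to 6416, permutation p = 2e-05, the smallest the resamples can give), 5452 bp in replicate 1 and 5662 bp in replicate 2. Of the forebrain TFs, 37 had more bp covered than Gbx2, a regulator of the midbrain-hindbrain boundary and by replicated peaks the highest of the other list. The lowest forebrain TF was Neurog1, a proneural factor named here after its value was seen, with 2358 bp. Mafb (5698 bp) and Egr2 (4161 bp), regulators of hindbrain segments, followed Gbx2. In the other lists Mafb lay above Gbx2, with 5907 against 4964 bp in replicate 1, 5584 against 4468 bp in replicate 2 and 6177 against 5731 bp in the pooled list.

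The 39 Hox genes, unmarked ones included, had 537 ± 496 bp (SD over genes), and the difference to the forebrain TFs was 7493 bp (6870 to 8072, permutation p = 2e-05, again the smallest possible). All 41 forebrain TFs lay above Hoxa7, the highest Hox gene. The cluster means were 724 bp for Hoxa, 399 bp for Hoxb, 226 bp for Hoxc and 772 bp for Hoxd, and 5 of 11, 2 of 10, 2 of 9 and 7 of 9 genes were marked. Hoxa9 (chromosome 6, 52223100 to 52231089) had no peak within 1 kb of its TSS and 755 bp within 5 kb. Neighbouring Hox genes share windows and are not independent. With the 4 clusters as units, chosen after the data had been seen, the difference was 7500 bp and the exact permutation p = 1.34e-05, the smallest these units can give. That test sets means of clusters against single genes, whose spreads are unlike.

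**Figure D3:**
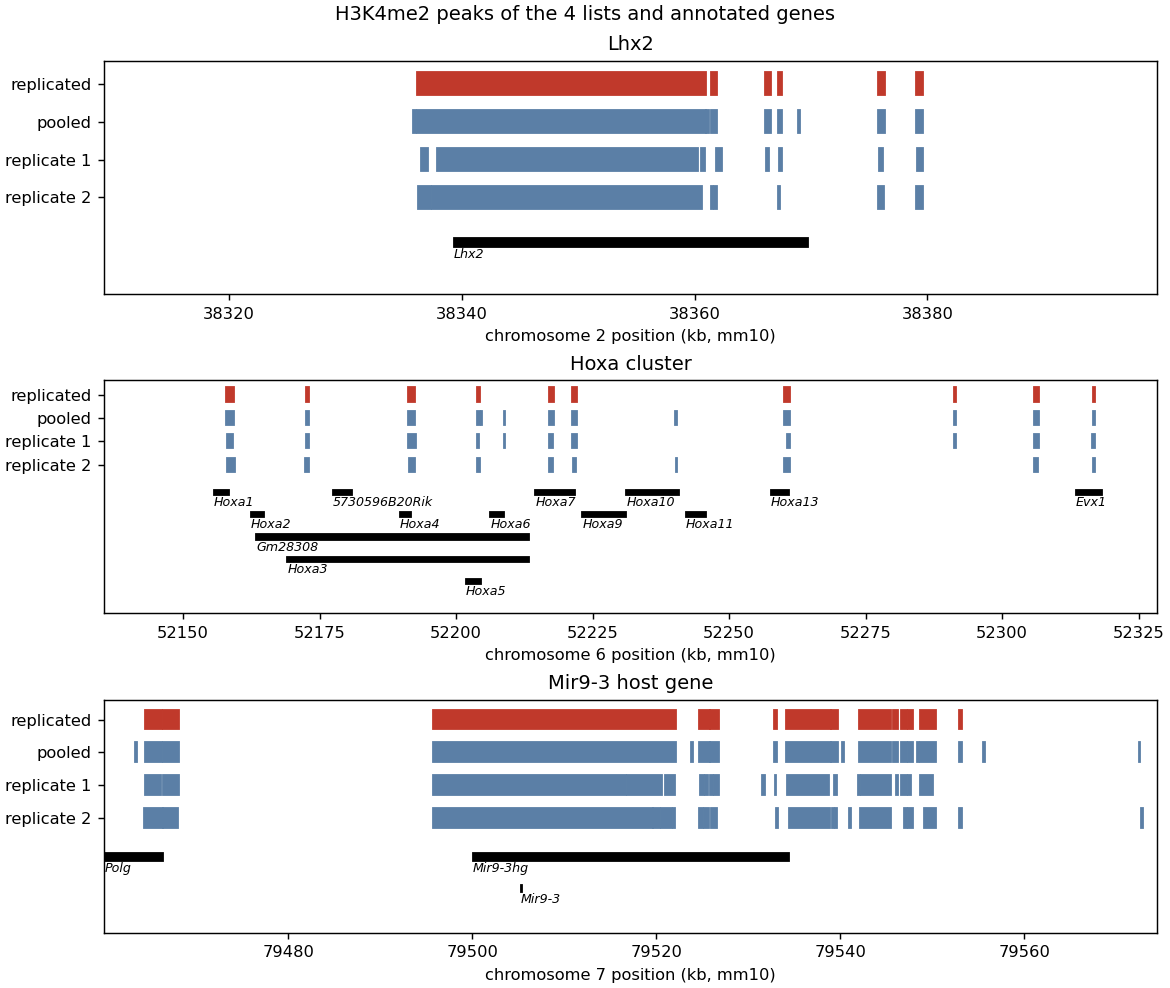
Peaks of the 4 lists (coloured boxes) and annotated genes (black bars) at Lhx2 on chromosome 2, the Hoxa cluster on chromosome 6 and the Mir9-3 host gene on chromosome 7, with positions in kb. Replicated peaks cover 30.3% of the Lhx2 region, 39.8% of the Mir9-3 region and 4.18% of the Hoxa region.

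The 5 widest H3K4me2 peaks lay at microRNA-9 genes and at Lhx2, Nfib and Mn1. The widest replicated peak, 26469 bp (chromosome 7, 79495717 to 79522185), covered Mir9-3 and the start of its noncoding host gene, and held no protein-coding TSS. The next, 25833 bp (chromosome 3, 88197853 to 88223685), covered Mir9-1, again with no protein-coding gene inside. MicroRNA-9 is abundant in the embryonic brain and acts in neural progenitors. The following 3 held the promoters of Lhx2 (24781 bp, chromosome 2, 38336164 to 38360944), Nfib (24478 bp, chromosome 4, 82490850 to 82515327) and the transcriptional regulator Mn1 (21508 bp, chromosome 5, 111413958 to 111435465). In replicates 1 and 2, peaks covered 25866 and 26055 bp of the Mir9-3 domain and 25247 and 25651 bp of the Mir9-1 domain, split into up to 5 peaks. Of 651 replicated peaks wider than 5 kb, 633 held a TSS and 589 a protein-coding one. These 651 peaks held TSSs of 44 of the 65 forebrain list genes, and of 625 of all 21826 protein-coding genes. Their widths are those of the pooled list, and the replicates' own lists held fewer peaks wider than 5 kb, 431 and 518.

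The peaks of highest signal value were narrower and lay at other promoters. The highest, 69.2 on the authors' scale, was a 4407 bp peak at Egr1, an immediate early gene (chromosome 18, 34859053 to 34863459). It was followed by peaks at Rreb1 (62.7), Nr3c2, the mineralocorticoid receptor gene (62.5), Acvr1c (62.4) and Epb41l3 (61.4), all with a midpoint within 1 kb of a TSS. This order is that of the replicated list: in replicate 2 alone Epb41l3 (59.8) lay above Egr1 (58.9), and Rreb1 had 41.3. Coverage of the whole 10001 bp window was reached by 13 protein-coding genes. Besides the TFs named, these included Islr2 and Nrn1, which act in axon growth, and Pcdh19, a protocadherin gene of chromosome X.

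Away from promoters, H3K4me2 sites clustered around neural regulators. Within 100 kb of their TSS, dorsal forebrain TFs had a mean of 5.52 distal peaks, cortical neuron TFs 4.75, ventral forebrain genes 3.83, radial glia genes 3.38 and pan-neuronal genes 2.32, whereas other genes averaged 1.21. Mid- and hindbrain TFs also had more, 3.33, while odorant and vomeronasal receptors had 0.179 and 0.125. In the replicates' own lists the dorsal TFs had 7.05 and 7.33 distal peaks and the mid- and hindbrain TFs 3.54 and 3.75. Of 22 lists, 8 were called by the permutation test, 6 higher and 2 lower. The adjusted permutation p was 3.67e-05 for the dorsal, cortical, ventral, mid- and hindbrain, odorant and vomeronasal lists, from the smallest p the resamples can give. The test took genes as independent, although neighbouring genes share windows and peaks, as receptor genes in clusters do. The adjusted permutation p was 0.000754 for radial glia and 0.0333 for the pan-neuronal list, whose call was lost with stricter peaks (1.79 distal peaks, adjusted permutation p = 0.0643) and with 50% overlap in each replicate (1.74, adjusted permutation p = 0.0938). Stricter peaks left fewer distal windows in all, 9958 against 12779, so the lower mean is not by itself a smaller excess over other genes.

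Hox genes (1.15 distal peaks) did not stand out within 100 kb (adjusted permutation p = 0.898), but within 250 kb they had 5.56 and were called higher (adjusted permutation p = 0.00066). In that wider window uncalled lists also had more distal peaks than within 100 kb, 3.4 for erythroid and 2.95 for mature synapse genes. Compared with other genes in the same window, the erythroid mean was higher and the mature synapse mean lower. Values within 250 kb are therefore not to be read against the 1.21 within 100 kb. Genes of a Hox cluster share peaks at that distance, the test took them as independent, and no test with clusters as units was run for it. Microglia genes had 2.2 distal peaks (adjusted permutation p = 0.0811), and were called higher in replicate 1 alone (3 distal peaks), in the pooled list (3.4) and within 250 kb (6.6), with adjusted permutation p-values of 0.0437, 0.0244 and 0.0022. Here too the test took genes as independent, although genes that share a window share peaks. The median of the list was 1 distal peak, while C1qa had 6, so a few genes may carry the mean. The fibroblast and mural, endothelial, choroid plexus, mature glia, mature synapse, liver, erythroid, striated muscle, epidermal, housekeeping, cell cycle and methylation machinery lists were not called. In the genome-wide ranking only the first gene alphabetically was kept where windows overlapped, so each name stands for a neighbourhood. The most distal peaks genome-wide lay around Btn2a2, Dand5 and Trim27 with 17 each, Cbx8 and Tcf20 with 16, and Foxp4, Gli3, Irf2bpl and Ncor2 with 15. Bcl11b, a TF of deep-layer cortical neurons, followed with 14. This order depended on the list: in replicates 1 and 2 alone Dand5 had 30 and 34 distal peaks, Bcl11b 31 and 22, Btn2a2 21 and 21, and Trim27 18 and 16.

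Motifs of several TF families, neural and general, were more frequent in distal peaks than in matched windows. The homeodomain core TAATTA occurred in 17.7% of the 12779 distal windows of 500 bp and in 7.62% of windows matched on chromosome and GC content, a ratio of 2.33. The POU octamer ATGCAAAT was found in 5.34% against 2.36%, the RFX site in 1.39% against 0.25%, and the MEF2 site in 1.12% against 0.524%. The SOX core was found in 54.5% against 45.9%, and the E-box CAGCTG, bound by Ascl1, in 33.3% against 27.1%. The E-box CAGATG, bound by Neurog and Neurod factors, was slightly rarer than in matched windows, with 34.3% against 35.9%. AP-1 (6.68% against 8.05%) and GATA (4.89% against 5.62%) sites were rarer as well.

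By Fisher's exact test 9 of 15 motifs were more frequent and 3 less frequent in distal peaks. Adjusted exact p-values were 2.7e-132 for the homeodomain core, 2.17e-35 for the octamer, 3.21e-25 for RFX, 8.58e-43 for SOX, 5.39e-27 for CAGCTG, 3.22e-07 for MEF2 and 0.00982 for CAGATG. The CTCF core was found in 86 windows against 7, the NFI site in 18 against 2 and the NRF1 site in 29 against 11 (adjusted exact p = 4.6e-18, 0.000668 and 0.00958). The NFI ratio of 9 rested on few windows and was 3.5 in replicate 1 alone and 5.5 in replicate 2 alone. The adjusted exact p was 5.14e-05 for AP-1 and 0.0124 for GATA. The HNF4 (2 against 3 windows), REST (78 against 85) and ETS (25 against 17) sites were not called, with adjusted exact p-values of 1, 0.683 and 0.323. In windows of 200 bp the CTCF, NFI, NRF1 and GATA calls were lost, with adjusted exact p-values of 0.449, 0.364, 0.219 and 0.111. The shares there were 0.0938% against 0.0547% for CTCF, 0.0704% against 0.0313% for NFI, 0.0704% against 0.0235% for NRF1 and 1.74% against 2.06% for GATA. The GATA call was also lost in replicate 1 alone (adjusted exact p = 0.0891), and in replicate 2 alone the ETS site was called (0.0254 by the same exact test). With stricter peaks the NRF1 call was lost (0.241% against 0.11%, adjusted exact p = 0.051), and with windows at the summit the ETS site was called (adjusted exact p = 0.0459).

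**Figure D4:**
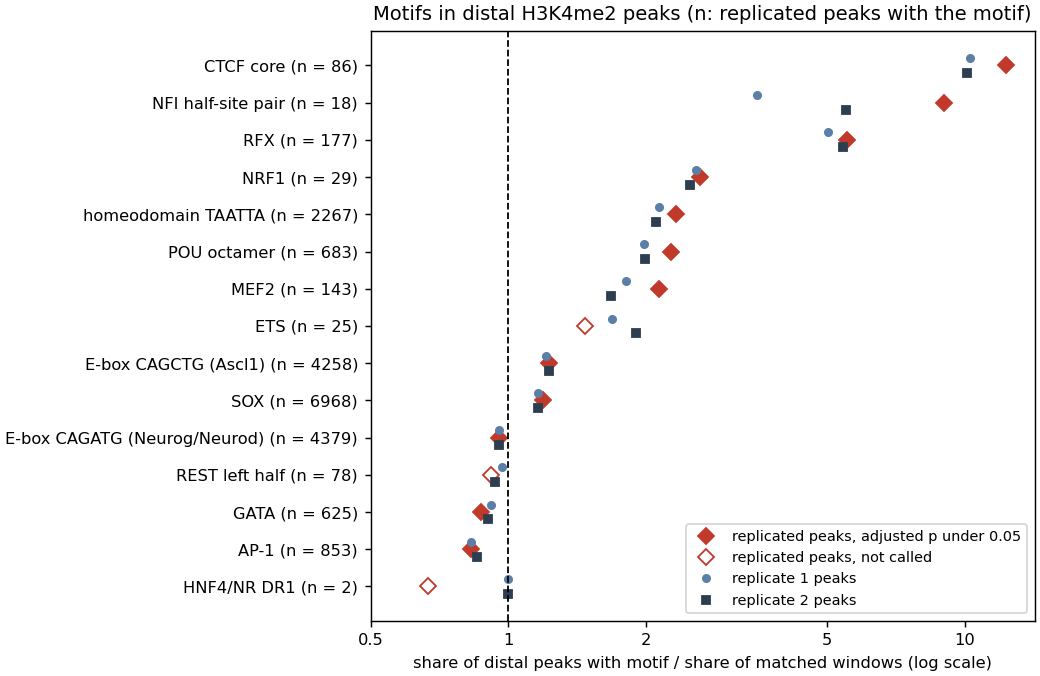
Share of distal peaks with each of 15 motifs divided by the share of GC-matched windows, on a log axis: diamonds are replicated peaks (filled where the adjusted p of Fisher's exact test was under 0.05), circles and squares the replicates' own distal peaks, and the dashed line marks a ratio of 1. RFX sites lie at 5.53, the homeodomain core at 2.33 and AP-1 at 0.829.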

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

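The comparison of CpG-rich Hox genes with other CpG-rich genes was planned as an alternative for every list, but its use among the tests of the Hox pattern was chosen after its result was seen. The replicated list held 13 peaks on unplaced or unlocalized scaffolds, a signal outside the chromosomes that the comparisons used.

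Forebrain TFs had more H3K4me2 around their TSSs than TFs of midbrain, hindbrain and spinal cord, and than Hox genes. More annotated TSSs per gene could account for only a small part of this. At the 5'-most TSS alone the difference to the first was 4713 bp instead of 5606 bp, and to Hox 6477 bp instead of 7493 bp (each with permutation p = 2e-05, the smallest possible). Longer CpG-rich stretches could not account for the difference to the first, since CpG-rich length was lower at forebrain TFs (2049 bp against 2325 bp). Regression on it raised the difference at the 5'-most TSS to 5295 bp (4410 to 6218, with the same smallest permutation p). Hox genes had less CpG-rich length (1703 bp), and regression lowered their difference to 5747 bp (5060 to 6451, again the smallest permutation p), so it could account for a small part there. That broad domains mark the regulators in use in this tissue remains a hypothesis, and no biological explanation was tested, since the data hold 1 tissue.

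Of 39 Hox genes, 16 were marked in forebrain. Hindbrain or spinal cord cells in the tissue may be a source, but the share of marked genes in groups 1 to 5 exceeded that in groups 9 to 13 by 2.92 percentage points (Fisher's exact p = 1), and with 15 and 16 genes this stays open. Of the marked Hox genes 75% had a CpG-rich promoter, against 69.6% of unmarked ones (Fisher's exact p = 1), which leaves a role of CpG content open too. A CpG-rich promoter was not enough for the mark, since 42.9% of CpG-rich Hox genes had it, against 98.8% of other CpG-rich genes (Fisher's exact p = 9.44e-24). This p-value took Hox genes as independent, although they lie in clusters, and no marking test with clusters as units was run. No biological explanation was tested.

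Peaks found in 1 replicate only made up 12.6% of replicate 1's list and 19.4% of replicate 2's. Weak peaks near the authors' threshold are a candidate explanation: among peaks with -log10 q of at least 5 these shares were 1.25% and 3.28%, at most 0.169 of the shares over all peaks. A difference in depth or in input files between the replicates stays open, since the files give no read counts, and no biological explanation was tested.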

How the results depend on the processing

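The tests with peaks overlapped over 50% in each replicate, CpG-poor promoters alone, a background matched on repeats and Hox clusters as units were chosen after the data had been seen. Of 1216 alternative values, 993 kept direction and call or moved less than a set limit, 144 moved further, 33 lost a call, 12 gained one and 34 reversed. Each value was counted once, so reversed values that also lost or gained a call are not among the 33 and 12. The set limit was not always the replicate SD, and for counts it was wider. Counts of 6 motifs against 9, and of 14487 marked genes against 14310 with a replicate SD of 33.9, were taken as within it. The 9 summary results gave 55 of 68 values within these limits and 13 that moved. Where no reason is given, the cause was not tested, and unknown depth limits what weak peaks can show.

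Replicate overlap was 77.9% at 50% of the peak's length, 69.1% at 50% of both lengths, 92.0% with stricter peaks and 96.9% for the 20000 peaks of lowest p. The share of peaks at promoters was 46.6% to 48.6% in either replicate alone, 43.4% in the pooled list, 55.8% with stricter peaks, 55.2% with peaks overlapped over 50% in each replicate and 58.0% of covered bp. Marking calls fell to 1 of 19 lists tested with CpG-rich promoters alone and to 6 of 21 with CpG-poor ones. With 98.7% of CpG-rich genes marked no list could be called higher, and several CpG-poor lists kept 2 or 3 members, all marked. The higher calls lost there therefore do not show a dependence on promoter class. The lower call of striated muscle did depend on it, since all 19 of its genes are CpG-poor. Their 26.3% stood against 65.6% of all other genes but 32.4% of other CpG-poor genes (adjusted exact p = 0.00139 and 0.847). All 15 erythroid genes are CpG-poor too, and their lower call was lost, though their 13.3% stayed below 32.4% (adjusted exact p = 0.206). Liver, microglia and epidermal genes, with 1 CpG-rich member each, lost theirs as well, at 5.88% to 7.14%. Coverage calls fell to 3 with CpG-poor promoters, where 7 lists had enough marked members for the test, against 16 among all genes. The forebrain TF differences ranged from 2074 to 9702 bp to mid- and hindbrain TFs and from 3399 to 11746 bp to Hox, the ends set by the window size.

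Reversals concerned lists that were uncalled under the alternative, except Hox distal peaks within 250 kb (5.56, adjusted permutation p = 0.00066), whose test took neighbouring genes as independent. Mature glia coverage reversed in each replicate alone (2573 to 2641.5 bp). In 1 replicate alone, fibroblast and mural marking reversed at 64.3% (range 64.3% to 78.6%), and distal peaks of these genes at 1.71 (1.21 to 1.71) and of striated muscle at 1.47 (1.47 to 2.05). With stricter peaks they were choroid plexus marking (58.3%) and distal peaks of liver (1) and of fibroblast and mural genes (1). With 50% overlap in each replicate they were fibroblast and mural marking (64.3%) and liver distal peaks (1.06). CpG-rich promoters alone gave 100% for few genes: 1 each of the epidermal, liver, microglia and vomeronasal lists, 3 of mature glia and 4 of endothelium. For the 19 such mid- and hindbrain TFs they gave 89.5%. In each case 98.7% of other CpG-rich genes were marked. CpG-poor promoters gave 36.4% for Hox and 35.7% for mature glia marking, and 1507 bp for mature glia coverage. A 10 kb window gave 2909.5 bp for mature glia and 3265 bp for mid- and hindbrain TFs, and a 2 kb window 1939 bp for mature glia. Distal peaks by nearest TSS gave 0.368 for methylation machinery, 1.07 for fibroblast and mural and 0.0526 for striated muscle genes. Within 250 kb they were 3.4 for erythroid and 2.95 for mature synapse genes, and within 50 kb 0.579 for machinery, 0.667 for liver and 0.579 for muscle. In 200 bp windows HNF4 (0.0156%) and REST (0.281%) reversed.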

Other observations

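The gene families below were chosen after the list results had been seen, and the tRNA test after the genes with most distal peaks had been seen but before its own result. Several families of axon guidance and patterning were marked more often than other genes: Eph receptors and ephrins in 22 of 22 cases, Wnt ligands in 19 of 19, semaphorins in 19 of 20, LIM homeodomain factors in 12 of 12 and forkhead factors in 38 of 44. Adjusted Fisher's exact p-values were 0.00026, 0.00071, 0.00547, 0.0155 and 0.00547. Of their members, 81.8%, 73.7%, 75%, 83.3% and 79.5% had CpG-rich promoters, a class marked in 98.7% of cases. Fgf ligands (19 of 22), POU (11 of 15) and T-box factors (9 of 13) were not called (adjusted exact p = 0.0528, 0.628 and 1). The 5 Zic genes, TFs of the dorsal midline and cerebellum, were all marked with a mean of 9220 bp covered, though the family was not called for marking (adjusted exact p = 0.199). Sox TFs (17 of 19, adjusted exact p = 0.0375) averaged 5693 bp and clustered histone genes (60 of 67, 2.86e-05) 4933 bp. For the histone genes too, the test and the mean took genes as independent, although neighbours can share a peak and a window.

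Genes related to complex I (46 of 46), to cytosolic ribosomal proteins (79 of 82) and to the proteasome (37 of 39) were nearly all marked. Most had CpG-rich promoters, and adjusted Fisher's exact p-values were 1.38e-08, 6.01e-11 and 5.11e-05. The complex I set was not limited to subunits, since it held Ndufaf3 and Ndufa4l2. Clustered protocadherins, surface proteins of neurons, were marked in 14 of 56 cases (adjusted exact p = 2.19e-09) and had CpG-rich promoters in 5.36%, where CpG-poor genes at large were marked in 32.4%, with the widest coverage including Pcdhgc4 and Pcdhac2. The exact test took these neighbouring genes as independent. Interleukins (7 of 31), keratins (6 of 49), keratin-associated proteins (1 of 57), beta defensins (0 of 42), cytochromes P450 (24 of 100) and taste receptors (1 of 38) were rarely marked. In these families 0% to 10% of genes had CpG-rich promoters. Interleukins (22.6%) and cytochromes P450 (24%) lay not far below the 32.4% of CpG-poor genes at large. On chromosome X 51.2% of genes were marked, but 97.0% of those with CpG-rich promoters.

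At marked genes with an isolated TSS, 62.2% of summits near CpG-rich promoters lay over 200 bp downstream of the TSS and 15.9% within 200 bp. For CpG-poor promoters these shares were 55.7% and 31.7%.

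Many distal peaks lay around Btn2a2 and Trim27 on chromosome 13. As a hypothesis, tRNA genes that the annotation used does not hold may account for them: 29 of these 34 distal peaks, or 85.3%, lay within 1 kb of a RefSeq tRNA gene, against 0.907% of all distal peaks. Of 403 tRNA genes, 248 had a replicated peak within 1 kb. No biological explanation was tested.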
